A study of Mus musculus with 18 samples.

How the data were processed

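RNA of micro-punched brain tissue was measured by total RNA sequencing in 18 libraries of 6 groups with 3 mice each, named as in the labels (sham right 1, 2 and 3; contralateral left 1, 3 and 5; 4 h 2, 3 and 6; 1 day 1, 3 and 4; 3 days 1, 2 and 8; 10 days 1, 2 and 5). No library is a repeat of another. The labels do not say whether a left-side punch shares its mouse with a right-side library, such as control 1 or 3 of the same number. The fit treats all libraries as independent, except in an alternative that takes the number as a block. The source of the left-side punches is stated in different ways in the labels, as given with the results.

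Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0 and StringTie 1.3.4d were used with mouse genome build GRCm38. Those notes give no settings, gene annotation, strand handling or filter. The values are FPKM as the authors deposited them, with a column for each library and no further scaling between libraries stated. FPKM carries the length used for each transcript and the sum of all fragments, so a library with more mitochondrial or other abundant RNA has lower values for all other genes. The same file holds a p-value and a q-value per gene that the authors deposited without stating which groups were compared. They were not used in any test here; 1178 genes have a q-value under 0.05. The copy used here has 10485760 bytes and ends inside a line. It holds 34922 complete gene entries ordered by the authors' q-value, while the smallest p-value and its q-value together imply 38022, so about 3100 entries with the largest q-values were not analysed here. The last complete entries share a q-value of 0.908 (854 genes). Genes of the lists below that are not in the copy are Elane, Cd163, Reln, Myh11 and Ahsp.

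Identifiers were matched to gene names (34798 matched), and coordinates, biotype, exon length and GC content were taken from GENCODE release M21 on GRCm38. Depth per library was estimated. Values of 7410 single-exon genes of over 300 bases were multiplied by their length. The commonest low value was taken as 1 fragment, which gives a nominal number of fragments. The share of low values within 0.1 of a whole multiple of this step was 26.9% to 34.3%, the step itself included. Most values were thus not near a whole multiple, and the share for evenly spread values was not worked out. The depths are therefore rough, and no counts were derived from them. Near-identical genes (Hspa1a and Hspa1b, the H2 genes, neighbouring Ccl genes) can share reads, and their values are uncertain to that extent.

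Genes with an FPKM of at least 1 in 3 or more libraries were tested (14016). Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0; data.table, version 1.17.8), 1 mean per group over all 18 libraries, with empirical Bayes moderation (trend and robust). Contrasts between groups gave log2 fold changes, standard errors and p-values, adjusted by Benjamini-Hochberg over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. An F-test over the 4 contrasts of stroke groups with sham right gave genes that change at any time. The unit of replication within a group is the mouse. All 4 times share the sham right libraries, so the comparisons with them are not independent, and no overlap between them is given.

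The gene lists, 33 in number, were written before the data were examined. They cover immediate early, heat shock, hypoxia, cytokine, oxidative stress, p53, clotting, interferon, antigen presentation, cell cycle, cholesterol synthesis, lysosomal, scar matrix, respiratory chain and mitochondrial genes, and markers of neutrophils, macrophages, lymphocytes, red cells, microglia, astrocytes, neurons of several kinds, cortical layers, oligodendrocytes and their precursors, endothelium, pericytes and choroid plexus. Only 4 neutrophil markers, 3 lymphocyte markers and 5 red cell genes passed the filter. Lists were tested with camera (correlation between genes preset at 0.01), again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Benjamini-Hochberg adjustment was over the lists of a comparison. Members were counted by the call over all genes and by adjustment over the list alone.

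The genes named were set by a rule written before the data were examined. For each time against sham right these are the 5 largest rises and 5 largest falls among called genes whose 3 stroke values all lie beyond the 3 sham values and whose higher mean reaches 1 FPKM, the 2 members with the smallest adjusted p in the direction of the list for each of the 10 lists with the smallest camera p, and a fixed panel of 46 genes. For the other comparisons they are the 3 largest rises and falls and the panel. Members of lists with 5 or fewer calls could be named as well. Maff at 4 h, members named where 5 or fewer were called in 1 direction only, and Ttr were chosen after their values were seen.

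The fit was tested on simulated data built from the sham means and the estimated spread, with 100 genes changed by a log2 fold change of 1 and 100 by 2. Of the first, 81 were recovered at 4 h, 79 at 1 day, 76 at 3 days and 85 at 10 days. Of the second, 100, 97, 100 and 100 were recovered. False calls numbered 9, 8, 13 and 8 among 14016 genes. The changes were added on the log2(FPKM + 1) scale whatever the level of the gene, so lowered genes could go below 0. For genes with low FPKM such a change is larger than the same fold of FPKM, so recovery does not carry over to them. The simulated noise was independent between genes and libraries, with the same spread in every library. The real libraries share an axis of differences within groups and some stand apart, so recovery and false calls there can differ.

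Alternatives fixed before the data were examined were a log2 fold change of at least 1, an adjusted p under 0.01, no filter, a minimum of 5 FPKM, a pseudocount of 0.1, the replicate number as a block, a fit of only the 2 groups, contralateral left or both control groups as control, and leaving out each library. Alternatives added after the data were seen were median-ratio scaling, leaving out the 37 mitochondrial genes with rescaling, quantile normalization, removing each library's trend on GC content and exon length, limma array weights, and leaving out contralateral left 5 with 10 day 5, or 4 h library 6. Alternatives that need read counts were not run because the deposited values are FPKM. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.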

Results

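Total RNA of a micro-punched piece of brain was sequenced from 9-week-old male C57BL/6 mice, an inbred laboratory strain. In photothrombosis a light-sensitive dye, rose bengal, is injected and a laser spot through the skull clots the vessels under it. Here the mice received 100 mg/kg of the dye 5 min before 15 min of green light (532 nm, 40 mW, 2 mm fiber) aimed 2 mm right of bregma, a landmark of the skull, and the punch was guided by magnetic resonance images of the lesion. The 18 libraries form 6 groups of 3, each from 3 animals, and whether a left-side punch shares its mouse with another library is not stated. These are the right side of sham mice, the lesioned right side at 4 h, 1 day, 3 days and 10 days, and a group of left-side punches. The protocol describes the left-side punches as coming from mice with a lesion, while their titles and disease state call them sham, and no time is given for them. They are called contralateral left here, and sham right is the control of every time point. The 5 comparisons with sham right ask which transcripts differ at each time and on the other side, and 3 further comparisons set each time against the one before.

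Values are FPKM, fragments per kilobase of transcript scaled by library total, and every fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Read totals were not used here. The commonest low value of single-exon genes, taken as 1 fragment, gives rough nominal depths from 12.6 M fragments (10 days, library 5) to 29.5 M (4 h, library 6). On that reading 1 fragment on a transcript of 1 kilobase would stand for 0.0796 to 0.0339 FPKM. Between 12118 and 13632 of the deposited genes reached 1 FPKM in a library. Mitochondrially encoded transcripts took 24.4% to 44.6% of the summed FPKM, the most in 10 day library 5. The mean correlation of a library with the others of its group, across genes, ran from 0.933 (10 day library 5) and 0.941 (contralateral left library 5) to 0.988 (sham right library 3). Ttr, the transthyretin transcript of the choroid plexus, was under 1 FPKM in 3 libraries of 3 different stroke groups and between 60.2 and 625 FPKM in the other 15.

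**Figure D1:**
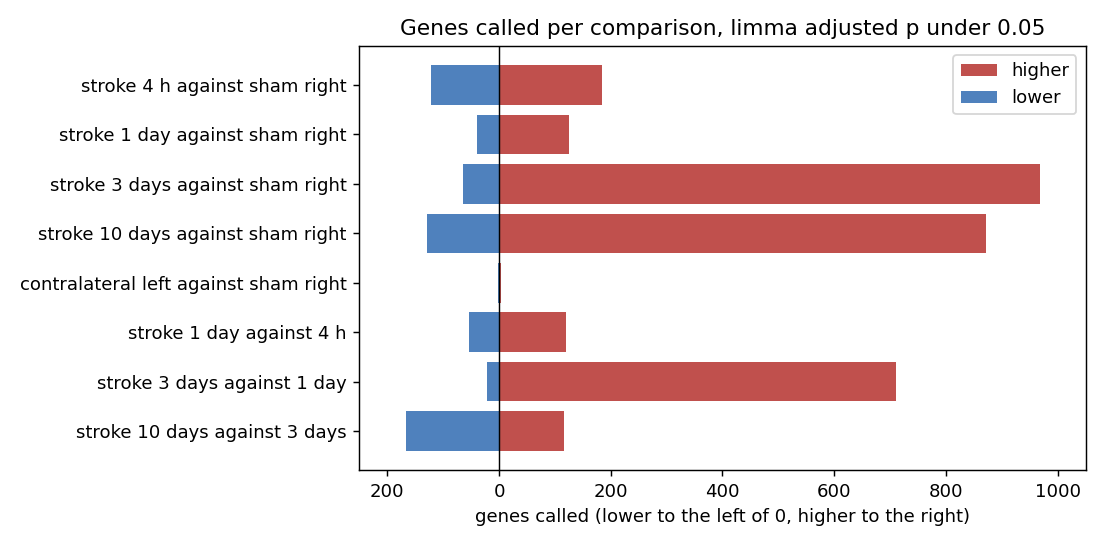
Genes called at a limma adjusted p under 0.05 in each comparison, out of 14016 tested, with genes higher in the first group drawn to the right of 0 and lower genes to the left. The 3 day and 10 day bars reach 968 and 871 higher genes against 185 at 4 h and 126 at 1 day.

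At 4 h after photothrombosis, single transcripts of chemokines and inducible chaperones were called higher than in sham right and several vessel transcripts lower, while no gene list held with an estimated correlation. Ccl3, a chemokine that attracts monocytes (ENSMUSG00000000982, protein-coding, chromosome 11, 83647844 to 83649355 in GRCm38), was at 9.11 ± 4.10 FPKM against 0.306 ± 0.141 in sham (SD, n = 3 in each group), a log2 fold change of 2.86 ± 0.39 (SE, limma adjusted p = 0.00134). Hspa1a, an inducible chaperone of the Hsp70 family, was at 23.6 ± 1.06 against 3.53 ± 0.174 FPKM, a log2 fold change of 2.44 ± 0.18 (limma adjusted p = 3.09e-06). Its near-identical neighbour Hspa1b gave 2.48 ± 0.19, and reads cannot be assigned with certainty between these copies. Of the genes that fell, Fabp7, a fatty acid binding protein of astrocytes and radial glia, went from 33.7 ± 3.27 FPKM in sham to 8.62 ± 0.851 (log2 fold change -1.85 ± 0.31, limma adjusted p = 0.00411).

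Among 12 measured inflammatory cytokines and chemokines, 5 rose at 4 h and 6 did so adjusted over the list alone. Ccl4, another monocyte attractant, rose by 2.67 ± 0.34 on the log2 scale, and Ptgs2, the inducible cyclooxygenase, rose as well. Of 12 p53 target and cell death genes, 3 rose (7 adjusted over the list alone), among them Cdkn1a, an inhibitor of the cell cycle (2.36 ± 0.35), and Gadd45b, a stress-induced gene (1.22 ± 0.17). Of 10 oxidative stress and metallothionein genes, 5 rose and none fell (6 higher and 1 lower adjusted over the list alone), with the metal-binding Mt2 at 1.17 ± 0.26. In the clotting and fibrinolysis list, 1 of 9 members rose by either count, Plaur, the urokinase receptor (1.56 ± 0.15). Of 16 hypoxia and glycolysis genes 2 rose (3 adjusted over the list alone), led by Adm, a vasodilator peptide induced by low oxygen (1.23 ± 0.13). Lcn2, an iron-sequestering protein of reactive glia, was the single member of 18 reactive astrocyte genes that rose (2.32 ± 0.30; 4 adjusted over the list alone). Of 12 heat shock chaperones, 3 rose by both counts (Hspa1a, Hspa1b and Hspb1), while the median of the list was -0.21 and its mean 0.30, and the list as a whole was not called (camera adjusted p = 0.324). The immediate early genes went both ways, with 5 of 22 higher, such as Maff (2.00 ± 0.20) and Atf3 (1.80 ± 0.20), and 2 lower (6 and 4 adjusted over the list alone). Fos itself was at 13.8 ± 2.34 FPKM against 14.9 ± 2.18 in sham.

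Of 15 endothelial and blood-brain barrier genes, 5 fell at 4 h and none rose, and 8 were lower and 2 higher adjusted over the list alone. Itm2a, a membrane protein abundant in brain endothelium, fell by 1.63 ± 0.19 on the log2 scale (15.2 ± 3.17 against 48.6 ± 2.65 FPKM), and Tek, the angiopoietin receptor, fell by 1.21 ± 0.16. The median of this list was -0.40 at 4 h and -0.44 in contralateral left, and in stroke 4 h against sham right with contralateral left as the control instead it was -0.15 (camera adjusted p = 0.214). Of 9 pericyte and smooth muscle markers none was called and 2 were lower adjusted over the list alone, with a median of -0.17 that became 0.15 with contralateral left as the control. Of 7 endothelial activation genes 3 rose and none fell (3 higher and 2 lower adjusted over the list alone), including Ch25h, cholesterol 25-hydroxylase (1.24 ± 0.20), and Angpt2, a vessel-destabilising ligand (1.09 ± 0.18). Of 12 homeostatic microglia markers 2 fell, Gpr34 and Sall1 (3 adjusted over the list alone), and all 12 lay below 0. Of 15 myelin genes 2 fell (4 adjusted over the list alone), Ugt8a and Opalin, and Aqp4, the water channel of astrocyte endfeet, was the single member of 14 resting astrocyte markers that fell (4 adjusted over the list alone). Gkn3, a gastrokine gene expressed in arterial endothelium, gave the largest fall of log2 fold change by the rule for named genes (-1.87 ± 0.23). None of 20 neuronal and synaptic genes was called by either count, and their median was 0.10. None was called by either count among 14 interferon-stimulated genes (median -0.28), 15 nuclear-encoded respiratory chain genes (-0.24) and 11 antigen presentation genes (-0.28) either. Sham right 1 was above the other sham libraries in the interferon-stimulated genes Isg15, Ifit1 and Irf7, which lowers their fold changes. Of 4 neutrophil markers none was called and 3 were higher adjusted over the list alone (median 1.17).

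In stroke 4 h against sham right, 306 of 14016 genes were called (limma, Benjamini-Hochberg adjusted p under 0.05), 185 higher and 121 lower, 107 of them with a log2 fold change of at least 1. By camera with a preset correlation of 0.01, 15 of 33 lists were called, 7 up and 8 down, and none held with an estimated correlation, with an adjusted p = 0.267 for the chemokine, endothelial, oxidative stress, clotting, hypoxia, neutrophil, resting astrocyte and homeostatic microglia lists, 0.102 for the p53 list, 0.566 for the reactive astrocyte, interferon, antigen presentation and pericyte lists, 0.652 for the myelin list and 0.743 for the respiratory chain list. The count was 163, 117 and 88 without sham right 1, 2 and 3 and 189, 135 and 162 without 4 h libraries 2, 3 and 6. In 1 or more of these fits the calls ended of Opalin (largest adjusted p = 0.228), Pfkfb3 (0.174), Ugt8a (0.128), Sall1 (0.112), Ccl2 (0.112), Hmox1 (0.109), Gpr34 (0.102), Srxn1 (0.0826), Fam168a (0.0624) and, without sham right 3, Aqp4 (0.0537). A fit of only these 2 groups called 844 genes, both control groups as the control 478, leaving out contralateral left 5 and 10 day 5 gave 1802, and the replicate number as a block 106. With contralateral left as the control 176 genes were called and Plin4 (adjusted p = 0.242), Gkn3 (0.0764), Tek (0.0901), Cdkn1a (0.0584) and Lcn2 (0.0662) were not among them.

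At 1 day, the cytokine and chemokine list and the reactive astrocyte list were the 2 of 33 lists that differed from sham right with an estimated correlation as well. Ccl12, a monocyte chemoattractant (ENSMUSG00000035352, protein-coding, chromosome 11, 82101845 to 82103400), was at 56.0 ± 14.9 FPKM against 1.16 ± 0.698 in sham (SD, n = 3 in each group), a log2 fold change of 4.73 ± 0.43 (limma adjusted p = 1.93e-05). Ptx3, a secreted pattern recognition protein, was at 25.5 ± 6.11 against 0.287 ± 0.0661 FPKM (4.33 ± 0.27, limma adjusted p = 2.41e-07), and Tgm1, a transglutaminase that crosslinks proteins, at 14.4 ± 4.51 against 0.0299 ± 0.0191 FPKM (3.86 ± 0.21, limma adjusted p = 7.01e-08). Gfap, the intermediate filament of astrocytes, reached 214 ± 70.7 FPKM against 48.9 ± 5.47 (2.06 ± 0.26, limma adjusted p = 3.63e-04). Hist1h1c, a linker histone, fell by 1.36 ± 0.23 on the log2 scale.

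Of 18 reactive astrocyte genes 10 rose at 1 day and 14 did so adjusted over the list alone, and all 18 lay above 0. Lcn2 rose by 4.27 ± 0.30 and Serpina3n, a serine protease inhibitor, by 3.00 ± 0.29, and Timp1, an inhibitor of matrix proteases, rose as well. Of 12 cytokines and chemokines 8 rose (9 adjusted over the list alone), with Ccl2, the main monocyte chemoattractant, at 3.68 ± 0.29. Of 10 oxidative stress and metallothionein genes 3 rose (6 adjusted over the list alone), with Hmox1, the heme-degrading enzyme, at 3.54 ± 0.39. Of 12 heat shock chaperones 3 rose by both counts, Hspb1 (1.84 ± 0.17), Hspa1a (1.37 ± 0.18) and Hspa1b (1.39 ± 0.19). Of 14 monocyte and macrophage markers 3 rose (6 adjusted over the list alone), Msr1, a scavenger receptor (1.67 ± 0.27), Fcgr1, an Fc receptor (1.05 ± 0.18), and Lgals3. Of 15 activated microglia and complement genes 2 rose (8 adjusted over the list alone), Cd14, the co-receptor for lipopolysaccharide (2.05 ± 0.23), and Cst7, a cystatin (1.07 ± 0.18). Of 9 clotting and fibrinolysis genes 2 rose (4 adjusted over the list alone), among them Plaur (0.87 ± 0.15). Of 7 endothelial activation genes 3 were higher, and over the list alone 3 were higher and 1 was lower. Itm2a fell by 1.29 ± 0.19, the single endothelial gene called among 15 by either count. Of 12 homeostatic microglia markers Fcrls rose by 1.13 ± 0.24, while over the list alone 1 was higher and 5 were lower and the median was -0.33. Of 15 myelin genes 1 fell (4 adjusted over the list alone), and the median was -0.50. Of 14 interferon-stimulated genes 1 rose by either count, Ifitm3, and of 16 hypoxia and glycolysis genes 2 rose by both counts. Of 22 immediate early genes 4 rose and 3 fell (4 and 8 adjusted over the list alone). None was called by either count among 5 red blood cell genes (median -0.65), 11 oligodendrocyte precursor markers (-0.14), 12 cortical layer markers (0.18) and 10 striatal projection neuron markers (-0.26). S100a8, the calcium-binding protein of neutrophils, was at 3.27 ± 2.05 FPKM against 0.615 ± 0.600, with a limma adjusted p = 0.254. In contralateral left 1, 3 and 5 it was at 2.40, 6.46 and 1.02 FPKM.

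In stroke 1 day against sham right 165 genes were called (limma, adjusted p under 0.05), 126 higher and 39 lower, 99 with a log2 fold change of at least 1. Of 18 lists called by camera (11 up, 7 down), 2 held with an estimated correlation, the reactive astrocyte and the cytokine lists (adjusted p = 0.00457 for both). The others had an adjusted p with an estimated correlation of 0.0582 for the oxidative stress and endothelial activation lists, 0.128 for heat shock and resting astrocytes, 0.159 for neutrophils, 0.189 for monocytes and macrophages, 0.191 for clotting and 0.214 for the activated microglia, homeostatic microglia, hypoxia and myelin lists. It was 0.367 for the interferon and red cell lists, 0.3998 for oligodendrocyte precursors, 0.535 for the choroid plexus and 0.624 for the striatal list. The count was 102, 88 and 84 without sham right 1, 2 and 3, and 155, 89 and 87 without 1 day libraries 1, 3 and 4. In 1 or more of these fits the calls ended of Opalin (largest adjusted p = 0.275), Arc (0.171), Myoc (0.164), Hk2 (0.131), Adm (0.0987), Gkn3 (0.0693), Lgals3 (0.0616) and Ifitm3 (0.0525). With contralateral left as the control the call of Itm2a ended (adjusted p = 0.0536). The replicate number as a block gave 62 calls, a fit of only these 2 groups 311, both control groups as the control 265, and leaving out contralateral left 5 and 10 day 5 gave 419.

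At 3 days, genes of cell division, phagocytes, astrocyte reactivity and interferon response were higher than in sham right. Spp1, osteopontin, a secreted phosphoprotein of activated phagocytes (chromosome 5, 104435118 to 104441050), was at 365 ± 137 FPKM against 13.3 ± 4.22 (SD, n = 3 in each group), a log2 fold change of 4.64 ± 0.50 (limma adjusted p = 1.28e-05). Lcn2 was at 29.1 ± 11.9 against 0.150 ± 0.0793 FPKM (4.64 ± 0.30, limma adjusted p = 2.14e-07), and Gfap at 434 ± 78.2 against 48.9 ± 5.47 FPKM (3.11 ± 0.26, limma adjusted p = 1.44e-06). Mki67, a marker of dividing cells, was at 5.81 ± 2.44 against 0.363 ± 0.0275 FPKM (2.26 ± 0.31, limma adjusted p = 1.29e-04).

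All 15 measured cell cycle genes rose at 3 days, by both counts. They include Rrm2, a subunit of ribonucleotide reductase (2.56 ± 0.23), Top2a, a topoisomerase of dividing cells (2.25 ± 0.24), and Cdk1, the mitotic kinase (1.75 ± 0.15). Of 18 reactive astrocyte genes 15 rose (16 adjusted over the list alone), with Vim, an intermediate filament, at 3.69 ± 0.24, Serpina3n at 3.94 ± 0.29 and Timp1 at 3.79 ± 0.48. Of 15 activated microglia and complement genes 13 rose (15 adjusted over the list alone), among them C1qa and C1qc, chains of the first complement component (2.47 ± 0.25 and 2.53 ± 0.24). Of 14 monocyte and macrophage markers 10 rose (12 adjusted over the list alone), with Lgals3, galectin-3, at 4.08 ± 0.34 and Cd68, a lysosomal protein of phagocytes, at 3.05 ± 0.29. Of 17 lipid handling and lysosomal genes 12 rose (13 adjusted over the list alone), including the cathepsins Ctsd (2.37 ± 0.18) and Ctsz (2.38 ± 0.17). Of 14 interferon-stimulated genes 10 rose (13 adjusted over the list alone), with Ifitm3, a restriction factor against virus entry, at 2.01 ± 0.23 and Oas1a, an oligoadenylate synthetase, at 1.90 ± 0.23. Of 11 antigen presentation genes 7 rose (9 adjusted over the list alone), with the class I genes H2-D1 (1.66 ± 0.19) and H2-K1 (1.65 ± 0.21), whose reads are hard to part from those of their paralogs. Of 12 homeostatic microglia markers 5 rose (10 adjusted over the list alone), and their median was 0.69.

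Hmox1 rose by 4.47 ± 0.39 on the log2 scale at 3 days, and 5 of 10 oxidative stress and metallothionein genes rose by both counts. Of 9 clotting and fibrinolysis genes 5 rose (6 adjusted over the list alone), with Plau, urokinase, at 1.35 ± 0.17. Of 12 cytokines and chemokines 6 rose (8 adjusted over the list alone), Ccl2 among them. Of 16 hypoxia and glycolysis genes 5 rose (6 adjusted over the list alone), with Adm at 1.05 ± 0.13. Of 15 scar matrix genes 5 rose (11 adjusted over the list alone), with Fn1, fibronectin, at 1.49 ± 0.25 and Col3a1, a fibrillar collagen, at 1.64 ± 0.38. Col3a1 was at 10.7 FPKM in 3 day library 8 against 1.80 and 3.60 in 1 and 2, its log2 fold change was 1.07 without library 8, and its call ended in a fit of only these 2 groups (adjusted p = 0.0787). Of 14 cholesterol synthesis genes 4 fell (6 adjusted over the list alone) and all 14 lay below 0, with Insig1, a sterol sensor, falling by 0.83 ± 0.12 and Idi1, an isomerase of the pathway, by 0.80 ± 0.17. The median of this list was -0.36 at 3 days and -0.31 in contralateral left, and with contralateral left as the control it was -0.04, Insig1 was at -0.45 and the call of Hmgcs1 ended (adjusted p = 0.718). None of the 20 neuronal and synaptic genes was called by either count, and Rbfox3, the neuronal nuclear antigen NeuN, was at 27.8 ± 2.65 FPKM against 28.1 ± 3.12. All 10 striatal projection neuron markers lay below 0, and none was called by either count. Of 15 endothelial genes 2 rose (4 adjusted over the list alone), Pecam1 and Vwf. Of 4 neutrophil markers 1 rose by both counts, Csf3r, a cytokine receptor (1.43 ± 0.20). In stroke 3 days against sham right the neutrophil median was 0.89, and it was -0.215 with contralateral left as the control. All 9 mitochondrially encoded mRNAs lay below 0 (median -0.31), and under quantile normalization this median was 0.05. Rn7s6, a 7S small RNA gene, was listed at 0 in all 3 libraries of 3 days and at 4.40 ± 1.61 FPKM in sham, so no fold is given.

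In stroke 3 days against sham right 1032 genes were called (limma, adjusted p under 0.05), 968 higher and 64 lower, 458 with a log2 fold change of at least 1, and under quantile normalization 678 were higher and 207 lower. Of 24 lists called by camera (15 up, 9 down) 12 held with an estimated correlation, among them the cell cycle list (adjusted p = 0.0350) and the cholesterol synthesis list (adjusted p = 0.0350), and 12 did not, among them the cytokine (adjusted p = 0.0590), hypoxia (0.134), scar matrix (0.198), striatal (0.369), mitochondrial (0.397) and neuronal (0.466) lists. Without 3 day library 8 the count was 647. The calls of Gm24270 (largest adjusted p = 0.286), C3 (0.285), Hspa1a (0.231), Hmgcs1 (0.201), Agt (0.157), Tmem119 (0.130), Irf7 (0.0683), Nts (0.0629) and Rn7s6 (0.0536) ended without 1 or more of sham right 1, 2 and 3 and 3 day libraries 1, 2 and 8. A fit of only these 2 groups called 1766 genes, and leaving out contralateral left 5 and 10 day 5 gave 1738.

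At 10 days, genes of activated microglia, lysosomes and antigen presentation were higher than in sham right, and cholesterol synthesis genes were lower. Cst7 was at 37.1 ± 4.09 FPKM against 0.104 ± 0.0176 (SD, n = 3 in each group), a log2 fold change of 5.10 ± 0.18 (limma adjusted p = 6.90e-11). Lyz2, the lysozyme of myeloid cells (chromosome 10, 117277331 to 117282321), was at 1012 ± 771 against 13.3 ± 3.39 FPKM (5.92 ± 0.47, limma adjusted p = 3.45e-07), and Gpnmb, a glycoprotein of lipid-laden phagocytes, at 37.5 ± 26.0 against 0.355 ± 0.135 FPKM (4.62 ± 0.37, limma adjusted p = 3.09e-07). Library 5 was above libraries 1 and 2 for both, with Lyz2 at 1900 against 624 and 512 FPKM and Gpnmb at 67.1 against 26.9 and 18.4. Col3a1 was at 30.0 ± 13.1 against 0.712 ± 0.0766 FPKM (4.10 ± 0.38, limma adjusted p = 1.59e-06). Arc, an activity-regulated gene of synapses, fell by 2.49 ± 0.26 on the log2 scale, from 82.7 ± 10.9 to 14.6 ± 6.61 FPKM (limma adjusted p = 4.87e-06).

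All 15 activated microglia and complement genes rose at 10 days, by both counts, with a median of 3.15. Clec7a, the receptor dectin-1, rose by 4.93 ± 0.31 and C1qa by 3.29 ± 0.25. Of 17 lipid handling and lysosomal genes 16 rose by both counts, with Ctsd at 3.28 ± 0.18 and Ctsz at 2.82 ± 0.17. All 11 antigen presentation genes rose by both counts, including B2m, the light chain of class I molecules (2.26 ± 0.21), and Cd74, the invariant chain of class II molecules (2.18 ± 0.45). Of 14 monocyte and macrophage markers 10 rose (12 adjusted over the list alone), with Spp1 at 5.87 ± 0.50 (2468 FPKM in library 5 against 502 and 432 in 1 and 2) and Cd68 at 3.87 ± 0.29. Of 12 homeostatic microglia markers 6 rose (9 adjusted over the list alone), with Fcrls, an Fc receptor-like protein, at 2.69 ± 0.24. Of 18 reactive astrocyte genes 12 rose (15 adjusted over the list alone), with Vim at 2.72 ± 0.24 and Gfap at 2.08 ± 0.26. Of 14 interferon-stimulated genes 10 rose (11 adjusted over the list alone), with Oas1a at 1.59 ± 0.23. Of 12 cytokines and chemokines 7 rose (8 adjusted over the list alone), with Il1a, interleukin 1 alpha, at 1.59 ± 0.19 and Ccl5, a T cell attractant, at 1.75 ± 0.21. Of 15 scar matrix genes 13 rose by both counts, with Col1a1, the main collagen of scars, at 3.42 ± 0.40 and Mmp2, a gelatinase, at 1.77 ± 0.18.

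Of 14 cholesterol synthesis genes 9 fell at 10 days (12 adjusted over the list alone) and all 14 lay below 0. Insig1 fell by 0.96 ± 0.12 on the log2 scale, Cyp51, a demethylase of the pathway, by 0.72 ± 0.11 and Hmgcs1, a synthase early in the pathway, by 0.84 ± 0.14. The median of this list was -0.76 at 10 days and -0.31 in contralateral left. With contralateral left as the control the median was -0.41, Insig1 was at -0.57 and Cyp51 at -0.42, and the call of Hmgcs1 ended (adjusted p = 0.0854). Of 22 immediate early genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.80 at 10 days and -0.44 in contralateral left, and with contralateral left as the control it was -0.35, with Arc at -1.54 and Nr4a1 at -1.04. Nr4a1, an orphan nuclear receptor, fell by 1.60 ± 0.23 and Fos by 1.74 ± 0.27, whose call ended with contralateral left as the control (adjusted p = 0.0616), while Atf3 rose by 1.87 ± 0.20. Of 15 cell cycle genes 2 rose and 11 did so adjusted over the list alone. None of 20 neuronal and synaptic genes was called by either count, 18 of them lay below 0 and the median was -0.31. All 11 choroid plexus and ependymal markers lay above 0 with a median of 0.49, none called by either count, and in stroke 10 days against sham right with contralateral left as the control this median was 0.05. Of 12 interneuron markers 1 fell by both counts, Calb2, calretinin (-1.54 ± 0.42). None was called by either count among 15 endothelial genes and 3 lymphocyte markers (median 0.37). Cd8a, a T cell co-receptor under the filter and so not tested, was at 0.289, 0.570 and 0.964 FPKM in 10 day libraries 1, 2 and 5 and at most at 0.0355 FPKM in the other 15.

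In stroke 10 days against sham right 1000 genes were called (limma, adjusted p under 0.05), 871 higher and 129 lower, 501 with a log2 fold change of at least 1. Of 19 lists called by camera (15 up, 4 down) 8 held with an estimated correlation, among them activated microglia and lysosomal genes (adjusted p = 0.00265 for both), antigen presentation (0.00802) and cholesterol synthesis (0.0266), while 11 did not, among them the scar matrix (adjusted p = 0.0518), interferon (0.109), immediate early (0.216), cell cycle (0.25), neuronal (0.385) and choroid plexus (0.575) lists. The calls of Disp2 (largest adjusted p = 0.270), Mki67 (0.102) and Irf7 (0.0733) ended without 1 or more of sham right 1, 2 and 3 and 10 day libraries 2 and 5. Without library 5, 826 genes were called, and with each library's trend on GC content and exon length removed library 5 lay above the mean of 1 and 2 by a median of 0.86 in the macrophage list, 0.785 in the scar matrix list and 0.291 in the activated microglia list.

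**Figure D2:**
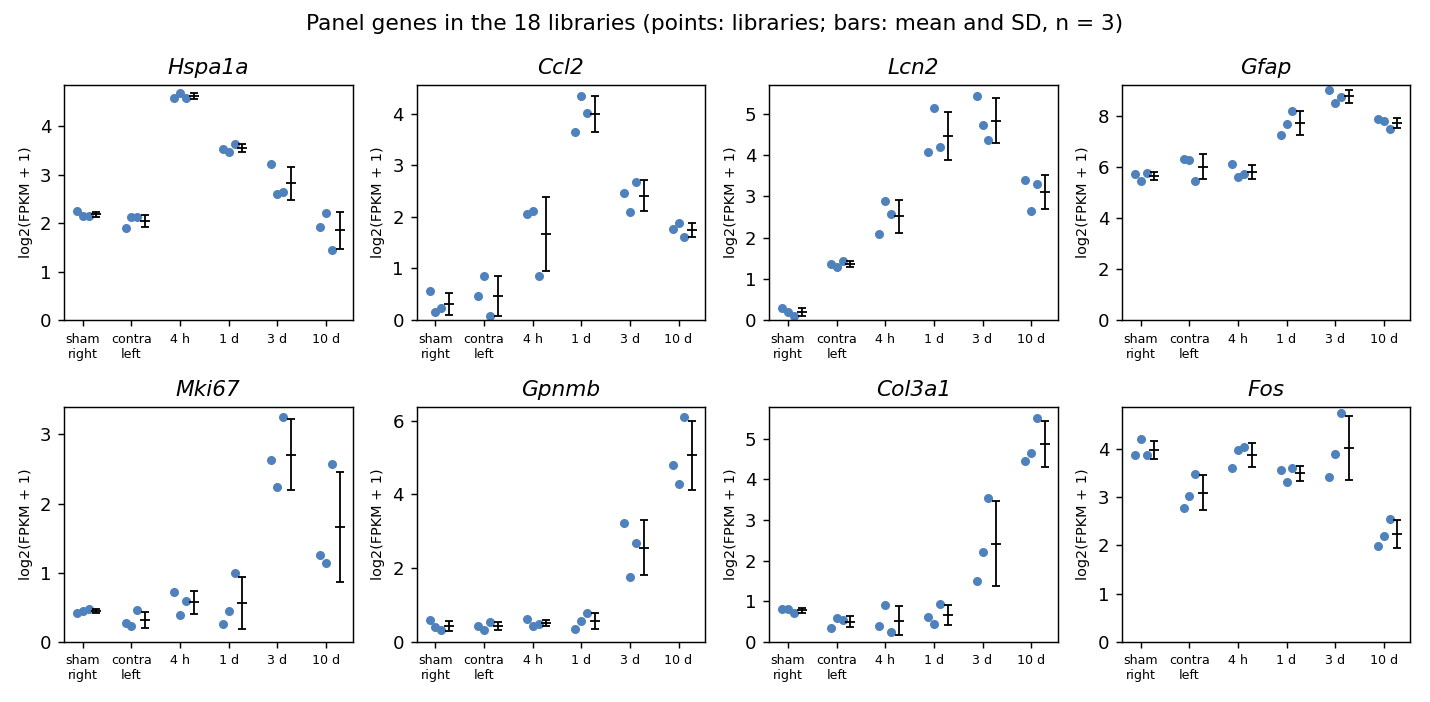
Log2(FPKM + 1) of 8 genes in each of the 18 libraries (points), by group, with the mean and SD of 3 libraries beside them. Hspa1a is highest at 4 h (23.6 ± 1.06 FPKM), Ccl2 at 1 day (15.3 ± 3.85 FPKM), Gfap and Mki67 at 3 days, and Gpnmb and Col3a1 at 10 days.

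Contralateral left punches were set against sham right to ask how the control sides differ. In contralateral left against sham right 4 genes were called (limma, adjusted p under 0.05), with 1077 at an unadjusted p under 0.05. Sult1a1, a sulfotransferase, was at 13.5 ± 1.68 FPKM against 3.90 ± 0.306 in sham right (SD, n = 3 in each group), a log2 fold change of 1.56 ± 0.24 (limma adjusted p = 0.0340). Smim3 (1.14 ± 0.17) and Tekt4, a tektin of ciliary microtubules (1.12 ± 0.16), were also higher, and Brinp3, a neuronal protein, was lower (-0.69 ± 0.11). None of the panel genes tested was called, with Lcn2 at 1.56 ± 0.119 against 0.150 ± 0.0793 FPKM (limma adjusted p = 0.383) and Fos at 7.68 ± 2.22 against 14.9 ± 2.18 FPKM (limma adjusted p = 0.476). No list member was called over all genes. Over the list alone, 5 of 14 cholesterol synthesis genes, 2 of 15 endothelial genes and 3 of 9 pericyte and smooth muscle markers were lower, with list medians of -0.31, -0.44 and -0.34. Of 22 immediate early genes 6 were lower and 1 higher over the list alone (median -0.44), of 10 oxidative stress genes 2 were higher, and 5 further lists had 1 such gene each. All 11 choroid plexus markers lay above 0 (median 0.46). Of 12 lists called by camera (6 up, 6 down) none held with an estimated correlation and none was called by fry (with an estimated correlation adjusted p = 0.274 for the cholesterol, endothelial and pericyte lists, 0.675 for the immediate early list and 0.490 for the choroid plexus list). Without contralateral left library 5 the gene count was 1212, 172 higher and 1040 lower, with the replicate number as a block it was 1, and without any other 1 of the 6 libraries it was 0, the calls of Sult1a1, Smim3, Tekt4 and Brinp3 ending with adjusted p between 0.123 and 0.293. The median-ratio scale was 0.8619 and 0.9099 in contralateral left 1 and 3, 1.044 in 5 and 0.9948 to 1.017 in sham right. Values of most genes are thus lower in contralateral left 1 and 3 as deposited. The count of 1212 was not run with scaling, so it does not give the number of differences between sides.

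From 4 h to 1 day, the reactive astrocyte list was the single list that held with an estimated correlation. Ptx3 went from 0.680 to 25.5 ± 6.11 FPKM (log2 fold change 3.97 ± 0.27, SE, n = 3 in each group, limma adjusted p = 8.92e-07), and of 18 reactive astrocyte genes 10 rose (14 adjusted over the list alone; camera adjusted p = 0.0406 with an estimated correlation). Ccl2 rose by 2.33 ± 0.29 on the log2 scale, 1 of 6 of 12 cytokines and chemokines that did (6 higher and 2 lower adjusted over the list alone; adjusted p = 0.199 with an estimated correlation). Serpina3n rose by 2.23 ± 0.29 and Gfap by 1.89 ± 0.26, while Hspa1a fell by 1.07 ± 0.18. Of 12 heat shock chaperones 1 rose and 2 fell (4 and 2 adjusted over the list alone). In stroke 1 day against 4 h 172 genes were called, 119 higher and 53 lower, and the split was 96 and 88 after median-ratio scaling and 91 and 100 after quantile normalization. The count was 93, 102 and 77 without 4 h libraries 2, 3 and 6, 69 and 96 without 1 day libraries 3 and 4, 13 with the replicate number as a block and 703 without contralateral left 5 and 10 day 5.

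From 1 to 3 days (stroke 3 days against 1 day), 732 genes were called, 711 higher and 21 lower, and all 15 cell cycle genes rose by both counts (adjusted p = 0.0174 with an estimated correlation). Ifi27l2a, an interferon-induced gene, rose by 3.70 ± 0.35 on the log2 scale, Fabp7 by 3.32 ± 0.31 and Spp1 by 3.50 ± 0.50 (SE, n = 3 in each group). Of 12 homeostatic microglia markers 9 rose (10 adjusted over the list alone; adjusted p = 0.0137 with an estimated correlation), and of 17 lipid handling and lysosomal genes 10 rose (15 adjusted over the list alone; 0.0137). Of 12 cytokines and chemokines 5 fell (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.0744 with an estimated correlation), with Ccl2 falling by 1.59 ± 0.29, Ccl7 by 1.75 ± 0.33 and Cxcl1 by 1.79 ± 0.25. Ptx3 fell from 25.5 ± 6.11 to 2.22 ± 1.37 FPKM. The count was 468 and 476 without 1 day libraries 1 and 3, 461 and 366 without 3 day libraries 1 and 8, 377 with the replicate number as a block and 1256 without contralateral left 5 and 10 day 5. It was 602 after median-ratio scaling and 493 after quantile normalization, with 588 and 460 of them among the 732. The split of 711 and 21 is that of values without such scaling.

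From 3 to 10 days (stroke 10 days against 3 days), 283 genes were called, 116 higher and 167 lower, with a median of -0.15 over all genes. After median-ratio scaling, with a median of -0.01, 159 were higher and 119 lower, and after quantile normalization 192 and 142. Clec7a rose by 3.87 ± 0.31 on the log2 scale and Cst7 by 3.22 ± 0.18 (SE, n = 3 in each group), among 7 of 15 activated microglia and complement genes that did (13 adjusted over the list alone; adjusted p = 0.0212 with an estimated correlation). Col3a1 rose by 2.46 ± 0.38 and Col1a1 by 2.23 ± 0.40, with 6 scar matrix genes of 15 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation). Of 15 cell cycle genes 11 fell (15 adjusted over the list alone; adjusted p = 0.0982 with an estimated correlation), with Top2a falling by 1.45 ± 0.24. Arg1, an arginase of alternatively activated macrophages, fell by 3.15 ± 0.30, Tgm1 by 3.42 ± 0.21 and Lcn2 by 1.73 ± 0.30. Of 22 immediate early genes 9 fell (17 adjusted over the list alone; adjusted p = 0.0982 with an estimated correlation), Fos by 1.78 ± 0.27. The count was 129 and 185 without 3 day libraries 1 and 2, 142 with the replicate number as a block and 3 when only these 6 libraries were fitted. Of the genes named here, Cst7 and Tgm1 kept their calls in all alternatives run. The calls ended in 1 or more for Clec7a (largest limma adjusted p = 0.1105), Arg1 (0.113), Lcn2 and Fos (0.184 for both), Top2a (0.204), Col3a1 (0.248) and Col1a1 (0.327).

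Over the 4 times, 1889 genes changed against sham right by limma's F-test (adjusted p under 0.05). The absolute fold change was largest at 4 h for 441 of them (241 higher, 200 lower), at 1 day for 125 (61 higher, 64 lower), at 3 days for 524 (508 higher, 16 lower) and at 10 days for 799 (708 higher, 91 lower). The largest value of a gene with noise at every time is placed by that noise too, so these counts describe the data and are not tests of when a gene peaks.

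**Figure D3:**
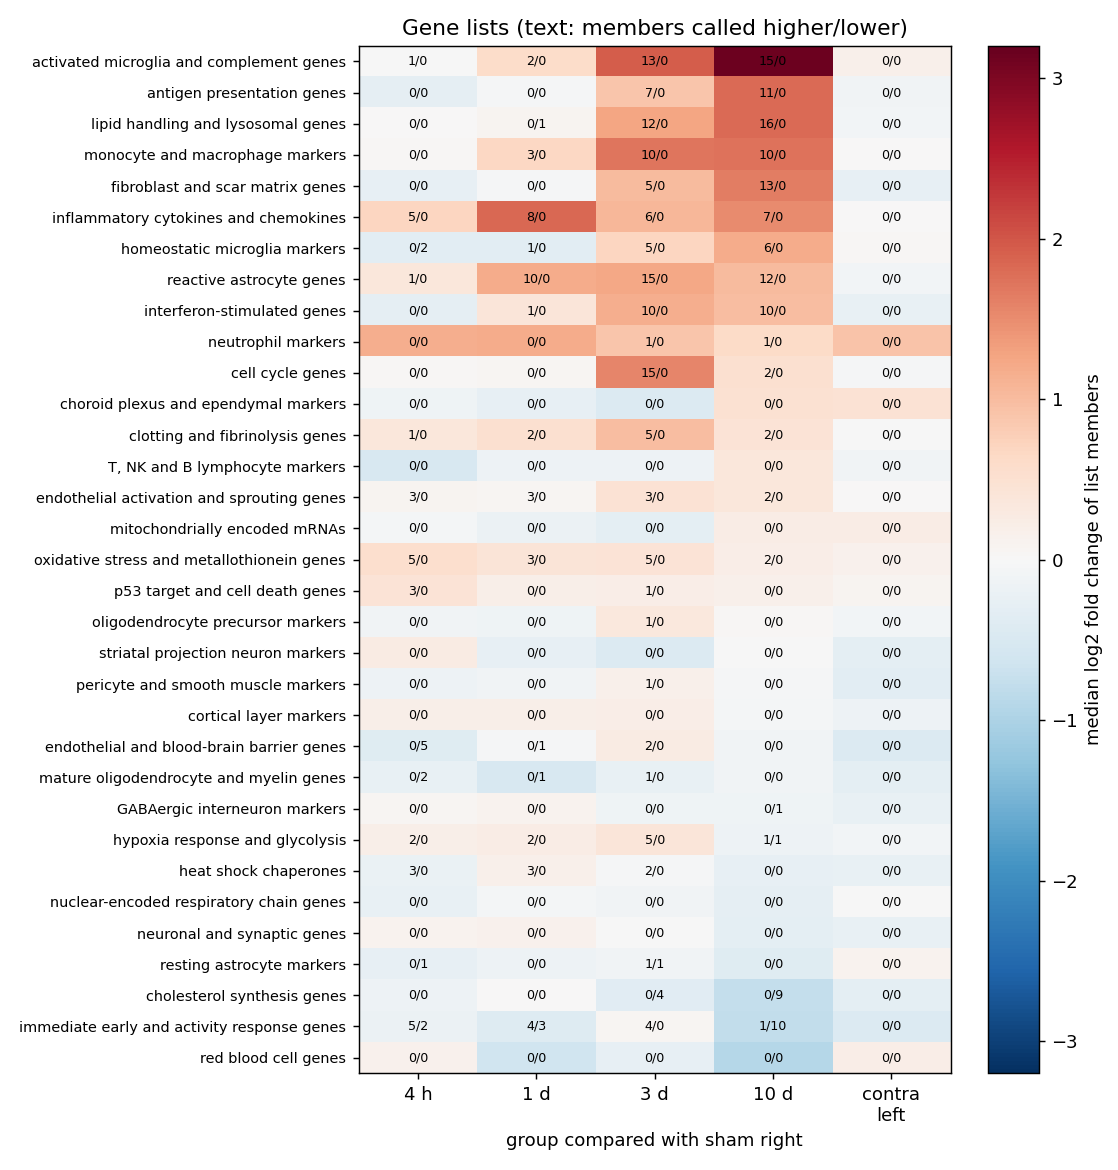
Median log2 fold change against sham right of the members of each gene list (colour), with the number of members called higher and lower in each cell, for the 4 times and contralateral left. The activated microglia list goes from 1 of 15 members called higher at 4 h to 15 at 10 days, and no member of any list was called in contralateral left.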

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

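The choice to leave the nuclear RNA explanation open was made only after its values were seen. Also chosen only after the result was seen were the test for more lesion tissue in 10 day library 5, the test for less vessel tissue at 4 h and the rule that picks the 3 genes below in its final form. They are named genes whose fold change against sham right had opposite signs at 2 times, both called, with a called difference between these times. Only genes named by the rule given with the processing were searched, not all genes tested. A first rule asked only for opposite signs and a called difference and gave 119 pairs of gene and time, so it was narrowed to pairs with both effects called, which left 3. Fabp7 fell by 1.85 at 4 h and was at 2.19 at 3 days, a difference of 4.04 ± 0.31 on the log2 scale (SE, limma adjusted p = 6.86e-07). For Gpr34 the values were -1.41 at 4 h and 1.83 at 10 days, a difference of 3.24 ± 0.29 (adjusted p = 1.19e-06). For Sall1 they were -0.63 and 0.79, a difference of 1.42 ± 0.14 (adjusted p = 2.18e-06). Both times share the sham right libraries, which cancel in the difference. The 4 h calls of Gpr34 and Sall1 ended without sham right 1, 2 or 3 or 4 h library 3 or 6 (adjusted p of up to 0.102 and 0.112).

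Libraries of a group part along a shared axis. The first component of the differences within groups holds 35.14% of their variance, with scores of -0.64 for contralateral left 5, -0.33 for 4 h library 6 and -0.27 for 1 day library 4 against 0.30 and 0.34 for contralateral left 1 and 3, and its gene loadings follow exon length (Spearman rho -0.468). Removing each library's trend on GC content and exon length left 0.8228 of the sum of squares, which argues against that trend as the whole cause. For a larger share of nuclear RNA in contralateral left 5, Malat1 differed by 2.86 while 4 other nuclear RNAs had a median of 0.1926. By the rule set beforehand, a median of 0.3 or less counts against this explanation. The 4 went both ways, from -0.41 (Neat1) to 1.14 (Miat), so the explanation is left open. That choice was made after these values were seen. Differences in RNA quality, library batch and punch position were not tested and stay open, and no biological explanation was tested.

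10 day library 5 stands apart from 10 day libraries 1 and 2. Its mean correlation with them was 0.9332 and became 0.9482 with the trend on GC content and exon length removed, under the bound of 0.952 set beforehand, which argues against that trend as the whole cause. A part in it stays open, since the second component within groups, on which library 5 scores 0.80, has gene loadings that follow GC content (Spearman rho -0.540). More lesion tissue in the punch may account for part, as library 5 was higher than the mean of 1 and 2 by a median of 0.8601 in macrophage markers and 0.7849 in scar matrix genes, but by 0.2914 in activated microglia genes, under the 0.5 the test asked for and above its bound of 0. With 1 such library, more lesion tissue cannot be told apart from a difference between animals, which stays open as untested. Library 5 also had the lowest rough nominal depth of all libraries (12.6 M fragments), the highest mitochondrial share (44.6%) and the lowest median-ratio scale (0.8457). Differences in RNA quality, depth and library batch were not tested here and stay open too.

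Endothelial and barrier transcripts lower at 4 h. With the trend on GC content and exon length removed, 5 of 15 were still called lower, which argues against that trend as the cause of the calls. Less vessel tissue in the punch would lower mural markers alike, and their median was above the endothelial one by 0.2301, with 8 of 9 mural markers below 0. This was hardly within an SE of 0.2308 that comes from resampling the genes of each list. Such an SE takes genes as independent and leaves out the spread between mice, so it cannot decide the question. Less vessel tissue may contribute, yet contralateral left itself had medians of -0.44 and -0.34 in these lists, and with it as the control the mural median of stroke 4 h against sham right was 0.1491. An early response of vessels to the lesion, as the design compares, stays open as untested.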

How the results depend on the processing

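Tests chosen only after the data were seen are median-ratio scaling, leaving out mitochondrial genes, quantile normalization, removing the GC and length trend, leaving out contralateral left 5 with 10 day 5 or 4 h library 6, and all counts of other splits. Main counts are 306, 165, 1032 and 1000 for 4 h, 1 day, 3 days and 10 days against sham right, 4 for contralateral left, 172, 732 and 283 for 1 day against 4 h, 3 days against 1 day and 10 days against 3 days, and 1889 for any change. Median-ratio scaling and removing the GC and length trend kept all counts within 1.5 times. No named gene changed sign under an alternative where it was called in the main fit or in that alternative. Changes of sign of genes called in neither were not counted. Of 2664 named-gene results with 1 library left out, 2445 kept their side of the threshold, 203 lost and 16 gained a call. These include genes not called in the main fit. Among called named genes, 10 of 27 at 4 h and 8 of 30 at 1 day lost the call in 1 or more fits. At 3 days 9 of 44 did, at 10 days 3 of 43 and in contralateral left 4 of 4. For the 3 steps between times it was 7 of 16, 6 of 21 and 2 of 18.

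In the order stroke 4 h against sham right, stroke 1 day against sham right, stroke 3 days against sham right, stroke 10 days against sham right, contralateral left against sham right, stroke 1 day against 4 h, stroke 3 days against 1 day, stroke 10 days against 3 days and any change over time, a log2 fold change of at least 1 left 107, 99, 458 and 501, and 74, 256 and 138 between times, by construction. An adjusted p under 0.01 left 106, 88, 673, 685, 0 (contralateral left, with 1077 at an unadjusted p under 0.05 in limma), 71, 435, 134 and 1244. The stricter filter left 156, 94, 427, 439, 2, 82, 285, 113 and 863, with fewer genes tested. The replicate number as a block gave 106 (4 h), 62 (1 day), 1 (contralateral left), 13, 377, 142 and 1135 (any change). A fit of only the 2 groups gave 844, 311 and 1766 for 4 h, 1 day and 3 days, 0 for contralateral left and 3 for 10 days against 3 days. Contralateral left as the control gave 176 at 4 h, and both controls 478 at 4 h and 265 at 1 day. A pseudocount of 0.1 gave 173 for 10 days against 3 days. For contralateral left, no filter and leaving out mitochondrial genes gave 0 and quantile normalization 2. Leaving out contralateral left 5 and 10 day 5 gave 1802, 419, 1738, 2767, 703, 1256 and 3262 for 4 h, 1 day, 3 days, contralateral left, the first 2 steps between times and any change. Of the lists called, 0, 2, 12 and 8 held with an estimated correlation at the 4 times, 0 in contralateral left and 1, 7 and 2 between times, and fry called 9 at 1 day, 0 in contralateral left and 5 for 1 day against 4 h. Where contralateral left 5 and 10 day 5 belong to neither group compared, leaving them out keeps every fold change. There it can act only through the shared spread and the filter. These libraries had the lowest mean correlations with their own groups (0.9412 and 0.9332). A shared spread is too wide for groups that are more alike and too narrow for the others. Except there and where the construction is named, the cause was not tested.

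Without 1 library at a time the counts ran from 88 to 189 (stroke 4 h against sham right), 84 to 155 (stroke 1 day against sham right), 647 to 1012 (stroke 3 days against sham right), 737 to 1125 (stroke 10 days against sham right), 0 to 1212 (contralateral left against sham right, the highest without its library 5), 69 to 123 (stroke 1 day against 4 h), 366 to 765 (stroke 3 days against 1 day), 129 to 298 (stroke 10 days against 3 days) and 1540 to 2029 (any change over time). Without 10 day library 5, 826 genes were called, 738 of them among the 1000. A group left with 2 libraries shares the spread of the others.

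Reversed lists, counted only where called in the main fit or in the alternative and the cause not tested, were these. With contralateral left as the control the median was 0.1491 for pericyte markers (stroke 4 h against sham right), 0.2865 for cholesterol synthesis (stroke 1 day against sham right), 0.3383 for heat shock and -0.215 for neutrophil markers (stroke 3 days against sham right) and 0.0501 for choroid plexus (stroke 10 days against sham right), where the test pointed down. With the block it was 0.3779 for choroid plexus genes (stroke 3 days against 1 day), and for immediate early genes the median stayed above 0 at 0.0536 and only the test turned down. Under quantile normalization it was 0.0536 for mitochondrial mRNAs at 3 days and 0 in stroke 10 days against 3 days.

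Leaving out mitochondrial genes moved the median of all genes to 0.10 at 4 h, 0.12 at 3 days and -0.21 for 10 days against 3 days, and contralateral left as the control moved it to 0.16 at 3 days. The array weights did not converge (42.5 for 1 day library 1), so that alternative could not be fitted, and those that need read counts were not run. Residuals of the 23 library pairs with the same number correlated by -0.227 to 0.409 (median 0.0374, against -0.0114 for different numbers), and 4 of 18 libraries matched best with their own number. No pairing was used in the main fit. The labels leave open whether left and right control punches 1 and 3 share mice, and values pooled over all pairs cannot settle it. At rough nominal depths of 12.6 to 29.5 M fragments, Il6, Tnf, Cxcl2 and most neutrophil and lymphocyte markers stayed under the filter.

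Splits of 3 against 3 number 10 and cannot give a share under 0.05, and in each comparison 1 split, the real one, called as many genes. The highest other split called 1 (4 h, 10 days and the 3 steps between times) or 0 (1 day, 3 days and contralateral left). For any change, 1 of 100 splits, the real one, gave as many as 1889, the highest other 352. This argues against chance labels for the count as a whole, and it is the smallest share that 100 splits can give. Other splits mix groups that differ, which widens the spread and lowers their counts, and no split tells a batch from a time. Groups did not overlap in 35.92%, 22.84%, 36.84%, 27.05% and 11.89% of genes at the 4 times and in contralateral left, where chance gives 10%.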

Other observations

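The 9 genes below were listed after Sgk1, Fkbp5, Plin4 and Cdkn1a had been seen among the rises at 4 h, but before their own values were seen, and no test of this part was chosen after its result. A response to glucocorticoid, the stress hormone, is a candidate explanation for such rises, and it asked for 4 or more of 9 further responsive genes to be called higher. At 4 h 7 were (9 adjusted over the list alone), with a median of 1.00 and all 9 above 0 (camera p = 2.44e-12, with an estimated correlation 0.0124). Those called were Tsc22d3, Klf9, Errfi1, Pdk4, Hif3a, Nfkbia and Angptl4, and Per1 and Zbtb16 were not. At 1 day, 3 days and 10 days 2, 2 and 1 were called higher. In contralateral left none was called (2 adjusted over the list alone), while all 9 lay above 0 with a median of 0.28 (camera with an estimated correlation, p = 0.0304). Several of these genes, such as Nfkbia, Angptl4, Errfi1 and Per1, also answer to other stimuli, and the time of day and handling of sham mice are not in the labels, so the hormone itself stays untested.

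Isg15, an interferon-induced gene, was at 18.4 FPKM in sham right 1 against 4.06 and 5.42 in the other 2 sham libraries. Ifit1 was at 7.226 FPKM there against 1.146 and 2.157, and Irf7 at 1.299 against 0.4246 and 0.52. A high sham value lowers the fold changes of these genes at every time against sham right. It can thus add to the fall of the interferon list at 4 h (median -0.28) and makes later rises smaller. The list was not tested without sham right 1.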
